A study of Cyprinodon variegatus with 15 samples.

How the data were processed

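MeDIP-seq was run on genomic DNA of whole sheepshead minnow larvae. Per the labels' protocols, 3 cups of 20 larvae were exposed per treatment in flow-through tanks at 30 °C, and each sample is a pool of 5 larvae. The labels do not say whether each pool came from its own cup, so p-values here measure the spread between these pools. Per the labels' protocols, 8 µg of DNA was cut with the restriction enzymes MseI and DraI, 3 µg was denatured and immunoprecipitated with an antibody against 5-methylcytosine, and libraries were made with the Accel-NGS 1S Plus and Methyl-Seq kit and sequenced as paired reads of 150 bp on a NovaSeq. Because fragment ends lie at restriction sites, the number of different fragments a window can give is limited. Such a limit caps counts only where duplicate reads were removed, and whether they were is not given in the sources used here. No input or spiked-in DNA library is among the 15 samples, so antibody enrichment could not be measured.

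Per the file headers, each of the 3 deposited tables holds raw counts of trimmed, paired reads for 2 groups of 3 libraries in windows of 100 bp. The tables share the same 10356462 windows on 9259 scaffolds, which cover 1036 Mb. Per the file headers, the authors also gave RPKM for each library, the mean count signal of each set of 3 libraries, and the log2 fold change, p-value and adjusted p-value of an edgeR test per window. The submitters' processing notes name edgeR with no version. The aligner, the genome build, the read filters and the edgeR settings are not given in the sources used here. The deposited p-value is missing exactly where the summed count of the 6 libraries is under 10. At the regions with the smallest p, the deposited adjusted p equals the p-value times the number of windows tested, as in a Bonferroni adjustment. That is stricter than the Benjamini-Hochberg adjustment used here. The normoxic control columns of the hypoxia and the oil plus hypoxia tables were identical, so each library entered once. Dividing the deposited counts by the RPKM gave the reads per library, and the total of counts over that number was 4.00 in every library, so each read was counted in about 4 windows. Neighbouring windows are therefore not independent. The header of 1 control column names a file of mapped reads where the others name a file of reads.

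Columns carry sample codes and not the sample titles. They were matched to the 15 samples through these codes and the table's own comparison, and no column of another sample was found (0 unused). Lane 2 is in the headers of all control, oil, normoxic control and hypoxia libraries and lane 3 in those of the oil plus hypoxia libraries.

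The comparisons are oil against control, hypoxia against normoxic control, oil plus hypoxia against normoxic control, oil plus hypoxia against hypoxia, and the 2 untreated groups against each other. They and the tests were fixed before the data were examined. Raw counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in the 6 libraries of each comparison, without a replicate block, after TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Windows entered above the lowest summed count, among 10, 20, 30, 60, 100, 200 and 400, that left at most 2000000 windows. This was 30 for oil and for both comparisons of oil plus hypoxia, 20 for hypoxia and for the untreated groups, and 60 over 12 libraries for the difference of the oil effects. The trend of the dispersion was estimated on 50000 randomly drawn windows. Standard errors are the log2 fold change divided by the root of the test's F. Called windows of one direction at most 500 bp apart were merged into regions. Levels are counts scaled to library size (CPM) and averaged over the windows of a region. Levels of a comparison use TMM-scaled library sizes and only the called (or, for the authors' regions, listed) windows of the region. Levels given for all 5 groups together use the total count of each library without TMM and every window between the region's start and end. The same region can therefore carry different values. Log2 values, standard errors and adjusted p-values of a region are those of its window with the smallest p.

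Named regions are the 5 merged regions with the smallest p in each direction, a rule fixed before the data were examined. Where the quasi-likelihood test called none, the same rule was applied to the authors' deposited table and its regions are given as values. For the difference of the oil effects, the 2 windows below 0 and the 1 above 0 with the smallest p are named, a choice made afterwards, as was that of single scaffolds. Regions singled out in the account of all 5 groups were chosen after their values were seen.

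The planned tests of promoters and gene bodies, of 15 lists of genes, and of CpG density were not run. The gene table used here names 24678 genes and gives a scaffold position for 0 of the nuclear ones, and no genome sequence was used. No region is therefore assigned to a gene, exon or intron. The planned test of the difference of the oil effects was moved from promoters to windows. Sums per scaffold (summed count of at least 60), the share of counts in the 1% of windows with the highest mean signal, the mitochondrial share the effect correlations over 1 kb bins (7 pairs of effects) and the overlaps of called windows were added after the data were seen.

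Each test was also run on simulated counts drawn from the real means, library sizes and fitted dispersion trend, with 200 windows or scaffolds changed. For oil it recovered 5.97%, 49.3% and 78.8% of windows changed 2-, 4- and 8-fold, and for hypoxia 1.49%, 22.4% and 54.5%. For oil plus hypoxia the shares were 4.48%, 41.8% and 66.7% against the normoxic control and 4.48%, 46.3% and 71.2% against hypoxia. For the untreated groups they were 5.97%, 38.8% and 60.6%, and for the difference of the oil effects, on 200000 windows, 1.49%, 31.3% and 57.6%. Between 1 and 3 unchanged windows were called in each simulation. Windows were drawn independently and on the trend, so reads shared by neighbours and spread particular to a window are absent. The shares hold for such sparse changes only. Per scaffold, 43.3% to 53.7% of 2-fold changes were recovered.

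Alternatives planned before the data were examined were DESeq2 size factors, the replicate number as a block, the neighbouring steps of the minimum count, 1 kb bins and leaving out each library. Alternatives added afterwards were lowess offsets by signal level (without and with the replicate block), thinning to the smallest library of a comparison, leaving out windows with a count of 200 or more, the edgeR exact test, DESeq2 1.42.0 on 1 kb bins, and a correction of counts for read positions already used. That correction assumes 798 possible positions per window, and 1596 for oil plus hypoxia replicate 1, whose highest count of 1466 exceeded 798. The header of that library names pool 2 (that of control replicate 1 names pool 1), and whether it joins more than 1 library is not known from the files. The true number per window is not known from the files. DESeq2 counts are given out of the bins to which it gave an adjusted p, which can be far fewer than those fitted.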

Results

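Methylated DNA was profiled in whole larvae of the sheepshead minnow (Cyprinodon variegatus), a small estuarine fish used in toxicity testing, after exposure to oil, to low oxygen or to both. The series asks which genomic regions carry altered methylation after an exposure has ended. Larvae were exposed for 48 h, held in clean water for another 48 h and sampled at 8 days post-hatch. Each of the 15 libraries came from a pool of 5 larvae, with 3 libraries in each of 5 groups. In MeDIP-seq an antibody against 5-methylcytosine captures methylated DNA fragments, so a read count rises with both the methylation and the number of methylated cytosines of a window, and it is not a methylation percentage.

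The control and oil groups formed 1 set, at a salinity of 15.8 ± 0.5 ppt. Oil, given in the labels as tPAH50 (a sum of polycyclic aromatic hydrocarbons), was 102.5 µg/L in the oil group and 0.3 µg/L in the groups without oil. A separate normoxic control (17 ± 2 ppt) served the hypoxia group (15.5 ± 1 ppt) and the oil plus hypoxia group (15.3 ± 1 ppt, 93.19 µg/L). The oxygen limit was at least 5 in normoxic groups and at most 2 in the hypoxic ones. Its unit is mg/L in the treatment protocol and mg/mL in the sample labels.

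Depth differed between the groups. The deposited RPKM values imply 8.40 ± 0.258 M reads per control library (SD, n = 3), 11.5 ± 0.674 M per oil library and 4.11 ± 0.921 M per normoxic control library. The hypoxia libraries held 5.98 ± 1.93 M reads, and the oil plus hypoxia libraries 16.1 ± 7.73 M, with 25.1 M in replicate 1. Total counts over all windows ran from 12265509 to 100146541 per library. Reads reached 32.9 ± 3.31% of the windows in the normoxic control and 57.7 ± 5.78% in oil plus hypoxia. Replicates correlated with r between 0.619 and 0.886 across 552317 bins of 1 kb, and bins are not independent replicates.

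Larvae exposed to oil were compared with control larvae to ask what oil alone left behind. No 100 bp window passed the test. The regions below are given as values. On NW_015150747.1, positions 434201 to 434500, signal was 1.30 ± 0.0749 CPM (counts scaled to library size) per window after oil and 0.367 ± 0.0441 in controls (SD, n = 3), with a log2 difference of 1.99 ± 0.25 (SE) at the leading window and an adjusted p of 0.347. On NW_015151779.1, 7001 to 7500, the levels were 0.811 ± 0.400 after oil and 0.0616 ± 0.0481 in controls (adjusted p 0.552). On NW_015151052.1, 407601 to 408000, the levels were 13.3 ± 0.737 and 18.2 ± 0.650, a log2 difference of -0.46 ± 0.08 (adjusted p 0.639).

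These regions were taken from the authors' deposited table, which lists 110 windows with an adjusted p under 0.05 in 49 merged regions, 8 higher and 41 lower after oil. That adjusted p is of the Bonferroni type (p times windows tested), so these counts and the Benjamini-Hochberg counts below rest on unlike thresholds. The remaining named regions with more signal after oil were NW_015152692.1 from 24101 to 24400 (0.364 ± 0.0862 against 0.0105 ± 0.0181 CPM), NW_015151572.1 from 91801 to 92000 (0.448 ± 0.103 against 0.0351 ± 0.0479) and NW_015150934.1 from 311301 to 311600 (0.386 ± 0.256, with no read in any of the 3 control libraries). Those with less signal were NW_015150865.1 from 769001 to 769600 (13 ± 0.679 against 18.0 ± 0.697), NW_015150975.1 from 60201 to 60600 (8.30 ± 0.553 against 11.8 ± 0.267), NW_015150482.1 from 1844801 to 1845300 (8.88 ± 0.60 against 12.5 ± 0.290) and NW_015152628.1 from 37901 to 38300 (7.61 ± 0.387 against 10.6 ± 0.307). With offsets that follow the signal level, the log2 differences of the 5 lower regions went from between -0.51 and -0.46 to between -0.12 and -0.03, and those of the 5 higher regions stayed between 2.01 and 6.92. The lower regions were among the most heavily covered of the genome. At NW_015150482.1 the highest count in a library was 504 in the controls and 506 after oil, although the oil libraries were deeper.

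Of 1623587 windows tested for oil, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, with 97486 at an unadjusted p under 0.05. The edgeR exact test, run on 3310682 windows with a summed count of at least 10, called 823 (161 higher, 662 lower). DESeq2, fitted to 535079 bins of 1 kb, gave an adjusted p to only 26754 of them and called 1154 (1 higher, 1153 lower). These 2 tests differ from the first in the windows or bins tested as well as in the method. Without oil replicate 1 the quasi-likelihood test called 12 windows, all lower.

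Hypoxia alone was compared with the normoxic control. No window passed the test here either. On NW_015150608.1, 363001 to 363300, signal was 0.477 ± 0.0471 CPM per window in hypoxia and 2.08 ± 0.0947 in the normoxic control (SD, n = 3), a log2 difference of -2.50 ± 0.31 (SE, adjusted p 0.434). On NW_015150752.1, 802201 to 802300, the levels were 0.633 ± 0.140 and 3.11 ± 1.01, a log2 difference of -2.29 ± 0.32 (adjusted p 0.728). Higher levels after hypoxia were measured on NW_015152481.1 from 49601 to 49700 (0.823 ± 0.209 against 0.0354 ± 0.0307) and on NW_015150504.1 from 1602901 to 1603000 (1.08 ± 0.165 against 0.148 ± 0.0950). The same held for NW_015150567.1 from 1364001 to 1364300 (0.752 ± 0.133 against 0.0342 ± 0.0592) and NW_015151041.1 from 435901 to 436000 (0.753 ± 0.137 against 0.0366 ± 0.0633).

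These 6 regions are all that the authors' deposited table lists for hypoxia at its Bonferroni-type adjusted p under 0.05, with 10 windows in them, 6 higher and 4 lower. edgeR's quasi-likelihood test called 0 of 1395191 windows, with 94455 at an unadjusted p under 0.05. The edgeR exact test called 91 of 2393540 windows and DESeq2 called 31 of 408118 bins of 1 kb. In data simulated at these depths with 200 changed windows, drawn independently, the quasi-likelihood test recovered 1.49% of those changed 2-fold. It recovered 22.4% of those changed 4-fold and 54.5% of those changed 8-fold.

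Larvae exposed to oil and hypoxia together differed from the normoxic control in 9387 windows, 3415 higher and 5972 lower. The higher windows had a median log2 difference of 1.39 and merged into 1689 regions, and the lower windows had a median of -0.72 and merged into 1919 regions. The loss with the smallest p was on NW_015151823.1, 57301 to 58000, where signal fell from 9.69 ± 0.403 to 4.42 ± 0.137 CPM per window (SD, n = 3), 2.19-fold, with a log2 difference of -1.16 ± 0.07 (SE) at the leading window and an adjusted p of 6.81e-06. On NW_015151052.1, 407401 to 408200, it fell 2.10-fold, from 22.6 ± 2.89 to 10.7 ± 0.323 (log2 -1.23 ± 0.08, adjusted p 6.81e-06). The gain with the smallest p was on NW_015152069.1, 34501 to 35000, where signal rose 2.26-fold, from 1.18 ± 0.134 to 2.67 ± 0.125 (log2 1.29 ± 0.16, adjusted p 0.000388).

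The other regions with the smallest p among the losses were NW_015150482.1 from 1844601 to 1845400 (2.14-fold), NW_015152321.1 from 65501 to 66300 (2.13-fold) and NW_015151252.1 from 170001 to 170800 (1.91-fold). Each had an adjusted p of 6.81e-06. Among the gains were NW_015150474.1 from 841001 to 841500 (2.23-fold), NW_015150477.1 from 933801 to 934300 (1.86-fold), NW_015150530.1 from 1140901 to 1141600 (2.28-fold) and NW_015150571.1 from 1181301 to 1181800 (1.93-fold), with adjusted p values between 0.000556 and 0.000819. The losses lay in strongly covered windows: 5411 of the 5972 lower windows were in the highest decile of signal, against 1855 of the 3415 higher windows. At NW_015151823.1 the highest count in a library was 371 in the controls, 372 after oil, 321 in the normoxic control and 309 in hypoxia, although these groups differed in depth, and 709 in oil plus hypoxia.

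The authors' deposited table lists 1705 windows for this comparison at its stricter, Bonferroni-type adjusted p, 525 higher and 1180 lower, and 1694 of them were also called here. The balance between directions moved between settings, which differ in the windows tested, in the method or in both. With a summed count of at least 20 in place of 30, edgeR called 4010 windows higher and 4378 lower, and with offsets that follow the signal level 3000 and 2421. Those offsets left the log2 differences of the 5 named losses between -0.89 and -0.58. The edgeR exact test called 23331 higher and 4528 lower of 3652240 windows with a summed count of at least 10, and DESeq2 called 14012 higher and 9068 lower of 595852 bins of 1 kb. Without windows holding a count of 200 or more the quasi-likelihood test called 6 higher and 43 lower. Of the main calls, 4411 of the 5972 lower and 1084 of the 3415 higher windows held such a count, so calls were lost in kept windows too. Oil plus hypoxia replicate 1 had 39949 windows with such a count, against 302 to 1225 in the normoxic control libraries. With 1 library left out the quasi-likelihood test called 2919 to 7530 windows, the fewest without normoxic control replicate 3. All oil plus hypoxia libraries were on lane 3 and all others on lane 2, so lane and exposure cannot be separated in any comparison with this group.

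**Figure D1:**
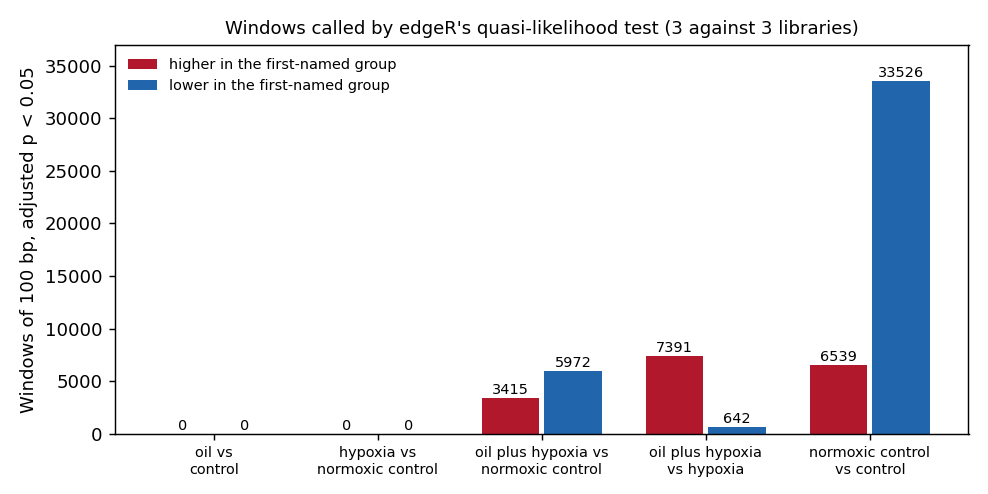
Number of 100 bp windows called by edgeR's quasi-likelihood test (vertical axis, linear) for each of 5 comparisons (horizontal axis), split into windows higher (red) and lower (blue) in the first-named group. Both single exposures gave 0 windows, oil plus hypoxia gave 3415 and 5972 against the normoxic control, and the 2 untreated groups differed in 6539 and 33526.

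Oil plus hypoxia was compared with hypoxia to ask what oil added under low oxygen. Of 8033 windows that differed, 7391 were higher and 642 lower with oil, in 3604 and 330 regions. With the replicate number as a block, 452 windows differed, 351 higher and 101 lower. With the block and offsets that follow the signal level, 6611 differed, 6018 higher and 593 lower. Signal at NW_015150752.1, 802101 to 802500, was 4.54-fold higher with oil, at 3.06 ± 0.0931 against 0.676 ± 0.268 CPM per window (SD, n = 3), with a log2 difference of 2.34 ± 0.24 (SE, adjusted p 0.0222). At NW_015150724.1, 712301 to 713000, it was 3.20-fold higher, at 3.74 ± 0.299 against 1.17 ± 0.36 (log2 2.37 ± 0.25, adjusted p 0.0222). At NW_015150564.1, 1207801 to 1208200, signal was lower with oil, at 0.0192 ± 0.00599 against 0.573 ± 0.205 (adjusted p 0.0222).

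Other regions higher with oil under low oxygen were NW_015150530.1 from 1491401 to 1491900 (3.59-fold), NW_015152282.1 from 92701 to 93500 (3.98-fold) and NW_015150773.1 from 184001 to 184500 (2.97-fold). Lower ones were NW_015150952.1 from 145201 to 145600 (0.0388 ± 0.0181 against 0.498 ± 0.0466 CPM) and NW_015152190.1 from 41901 to 42400 (0.0617 ± 0.0157 against 0.542 ± 0.247). NW_015151195.1 from 187601 to 187900 and NW_015156350.1 from 901 to 1100 held no read in any oil plus hypoxia library, against 0.445 ± 0.0831 and 0.431 ± 0.0914 CPM in hypoxia. The median log2 difference was 1.85 for the higher and -1.99 for the lower windows. The smallest adjusted p of the comparison was 0.0222. The test called 0 windows without oil plus hypoxia replicate 1, 2 or 3 or without hypoxia replicate 2, 2927 without hypoxia replicate 1 and 10095 without hypoxia replicate 3. Its windows at an unadjusted p under 0.05 numbered 357704 with all libraries and 380945 without hypoxia replicate 2. They numbered 243270 to 264072 without 1 oil plus hypoxia library. Summed into bins of 1 kb, 0 of 636961 bins passed edgeR's quasi-likelihood test. DESeq2 gave an adjusted p to 241761 of these bins and called 7634 (5266 higher, 2368 lower).

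Levels in all 5 groups, here relative to total counts without TMM scaling, show which library set a named region departs from. At NW_015150752.1, 802101 to 802500, signal was 0.733 ± 0.264 CPM per window in the controls, 0.825 ± 0.0736 after oil and 0.680 ± 0.290 in hypoxia, but 2.85 ± 0.877 in the normoxic control and 3.07 ± 0.0674 in oil plus hypoxia (SD, n = 3). At NW_015150724.1, 712301 to 713000, the hypoxia level of 1.18 ± 0.397 lay below 2.27 ± 0.0880 in the controls, 2.29 ± 0.437 after oil and 2.08 ± 0.582 in the normoxic control, and oil plus hypoxia lay above all of them at 3.75 ± 0.286. At NW_015152069.1, 34501 to 35000, controls (2.05 ± 0.252) and oil (2.21 ± 0.161) lay nearer to oil plus hypoxia (2.62 ± 0.128) than to the normoxic control (1.20 ± 0.130) or hypoxia (1.19 ± 0.214). These levels differ slightly from those of the single comparisons.

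**Figure D2:**
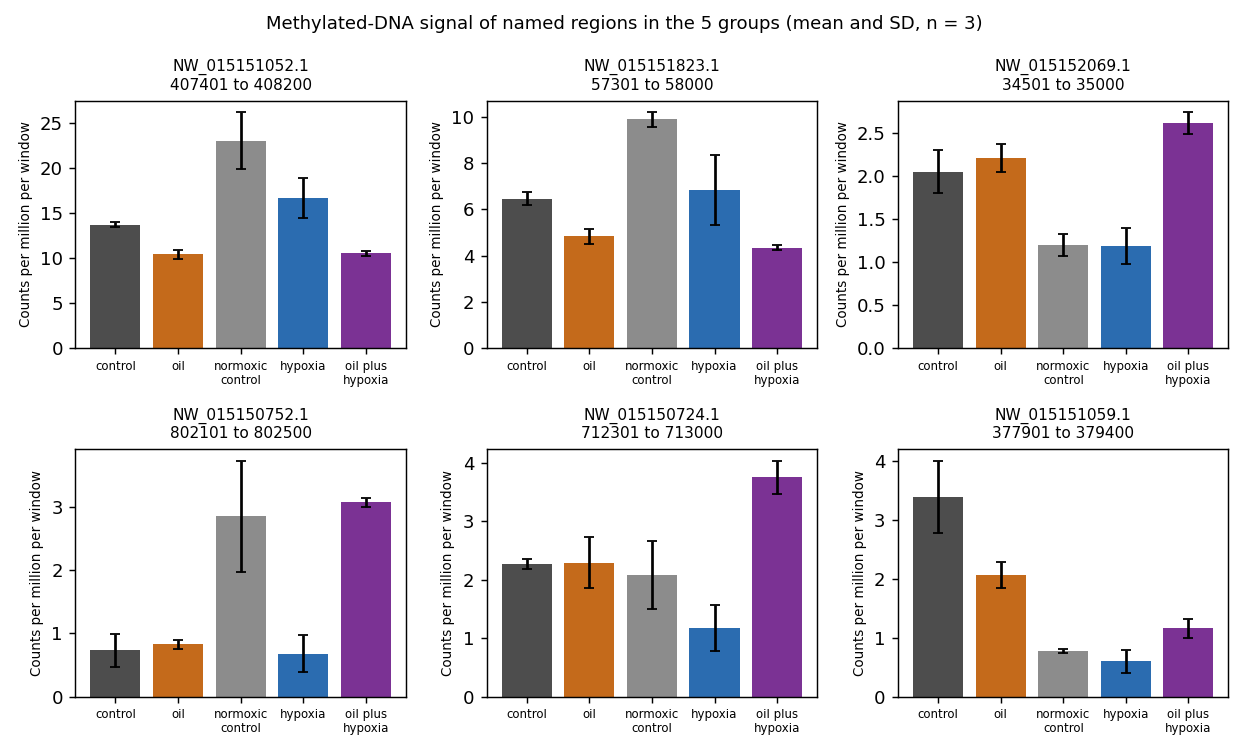
Signal of 6 named regions (panels, titled with scaffold and positions) in the 5 groups. Bars are mean CPM per 100 bp window over every window between the positions, relative to total counts without TMM scaling, on a linear axis. Error bars are SD over 3 libraries. At NW_015150752.1 the normoxic control (2.85) and oil plus hypoxia (3.07) stand above the other groups, and at NW_015151059.1 both untreated groups differ (3.39 in controls, 0.766 in the normoxic control).

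Whether oil acted differently at normal and low oxygen was tested directly, as the oil effect in normoxia minus the oil effect under hypoxia. This difference passed the test in 6930 of 1757501 windows, and it was below 0 in 6733 of them. In 6725 of these 6733 windows the oil effect under hypoxia was above 0, with a median log2 of 1.58, against a median of -0.48 for the oil effect in normoxia. Because these windows were selected by that difference in the same libraries, opposite signs are favoured and the medians are no separate evidence. At NW_015151042.1, 523101 to 523200, signal was 2.39 ± 0.945 CPM in controls and 1.32 ± 0.190 after oil, but 0.590 ± 0.113 in hypoxia and 2.30 ± 0.138 with oil under hypoxia (SD, n = 3; difference of the log2 effects -2.83 ± 0.37 SE, adjusted p 0.0183). At NW_015150585.1, 517701 to 517800, the 4 levels were 0.838 ± 0.307, 0.428 ± 0.0611, 0.0906 ± 0.0326 and 0.840 ± 0.105 in the same order (-4.05 ± 0.53, adjusted p 0.0183).

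In the opposite direction, NW_015150496.1 from 1196501 to 1196600 rose from 0.0398 ± 0.0176 in controls to 0.478 ± 0.167 after oil and was 0.417 ± 0.397 in hypoxia and 0.0775 ± 0.0280 in oil plus hypoxia (5.81 ± 0.95, adjusted p 0.0184). Of the 6930 windows, 3439 were also called between oil plus hypoxia and hypoxia. The test called 2211 windows with the replicate number as a block and 0 without oil replicate 2 or control replicate 2, and its contrast carries the lane of the oil plus hypoxia libraries.

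The 2 untreated groups, which differed in salinity and served different exposures, gave the largest number of called windows in the quasi-likelihood test. DESeq2 called 8539 bins of 1 kb between them, of 231670 that it gave an adjusted p among 418120 fitted. Between oil plus hypoxia and the normoxic control it called 23080 of 595852, among 595919 fitted. The numbers of bins given an adjusted p thus differed. In the same order, edgeR's quasi-likelihood test called 2945 and 249 bins of 1 kb, and 22969 and 2325 windows after thinning. Signal was lower in the normoxic control than in the control in 33526 windows (median log2 -1.66, 11999 regions) and higher in 6539 (median 1.52, 3616 regions). On NW_015151059.1, 377901 to 379400, signal was 0.859 ± 0.0595 CPM per window in the normoxic control and 3.95 ± 0.801 in the control (SD, n = 3), 4.59-fold lower (log2 -2.26 ± 0.17 SE, adjusted p 2.55e-05). On the same scaffold, from 370901 to 373500, it was 9.52-fold lower (0.294 ± 0.0812 against 2.80 ± 1.06). On NW_015151052.1, 407501 to 408200, it was 1.62-fold higher (25.1 ± 2.79 against 15.5 ± 0.776, log2 0.81 ± 0.10, adjusted p 0.000275). The highest count in a library there was 689 in the controls, 702 after oil, 639 in the normoxic control and 676 in hypoxia, although depth differed. In oil plus hypoxia it was 1466. With the correction for used positions the log2 difference at the leading window was 0.51.

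Further regions lower in the normoxic control were NW_015152957.1 from 20301 to 22300 (5.00-fold), NW_015150724.1 from 161201 to 162300 (3.04-fold) and NW_015151008.1 from 435101 to 437200 (4.76-fold). Higher ones were NW_015150865.1 from 768801 to 769700 (1.74-fold), NW_015151102.1 from 259401 to 259900 (1.90-fold), NW_015150823.1 from 788401 to 789000 (2.24-fold) and NW_015150752.1 from 802101 to 802500 (3.78-fold). At NW_015150865.1 too the highest count hardly followed depth, with 706 in the controls, 707 after oil, 657 in the normoxic control and 659 in hypoxia. In oil plus hypoxia it was 1402. Of the windows lower here, 1494 were also higher in oil plus hypoxia than in the normoxic control, where lists independent within 100 classes of equal signal would share 231, and of the windows higher here 905 were lower there, against 190. Both comparisons use the same normoxic control libraries, so part of this overlap can come from those libraries alone. Without normoxic control replicate 3 the count was 10308 windows, without replicate 2 it was 11416, and with the replicate number as a block it was 19858.

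Another overlap involved no shared library. Of the windows called higher in oil plus hypoxia than in hypoxia, 970 were lower in the normoxic control than in the control, against 403 for lists independent within those classes, and 52 were higher, against 48.7. Of those called lower, 13 were lower there, against 24.2, and 51 were higher, against 7.54. Neighbouring windows share reads, so these counts are not of independent windows. Across the 552317 bins of 1 kb, the oil effect in normoxia and the oil effect under hypoxia, which share no library, had a correlation of 0.0571 (0.0338 within classes of equal signal). That of the oil effect under hypoxia with control minus normoxic control, which have no library and no exposure in common, was larger, at 0.114 (0.0958 within classes). Each of these differences subtracts a group of lower mean depth, so these correlations and the overlap above also have a contrast in depth in common. Oil alone and the combined exposure had a correlation of 0.0745, which was 0.000359 within classes of equal signal. Hypoxia alone and the combined exposure had a correlation of 0.601 (0.564 within classes of equal signal), against 0.555 in simulated groups without any effect that share their controls, and a covariance of 0.451 against 0.221. The difference of control minus normoxic control, which holds no exposure but the same normoxic control libraries, had correlations of 0.680 with the combined exposure (0.564 simulated) and 0.513 with hypoxia (0.541 simulated). Its covariances were 0.511 and 0.430, against 0.22 simulated for each, so the excess is not particular to a shared exposure.

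A smaller share of the counts lay in signal-rich windows in the exposed libraries. The 1% of windows with the highest mean signal over the 15 libraries held 26.8 ± 1.5% of the counts in controls and 23.8 ± 1.07% after oil (SD, n = 3, exact permutation p = 0.1). They held 25.2 ± 0.562% in the normoxic control, 22 ± 1.96% in hypoxia and 22.3 ± 0.308% in oil plus hypoxia (exact permutation p = 0.1 for each against the normoxic control). Exposed and unexposed libraries did not overlap in these 3 comparisons. Oil plus hypoxia and hypoxia overlapped (exact permutation p = 1). All these tests are two-sided, 0.1 is the smallest p that 3 against 3 libraries allow, and the adjusted values over the 4 comparisons were 0.133, 0.133, 0.133 and 1. Permuted within both sets together, the summed difference of -6.13 percentage points was the largest of 1680 regroupings (exact permutation p = 0.000595, the smallest they can give). In all 3 comparisons of exposed with unexposed libraries the exposed group also had the higher mean depth. That p therefore does not separate exposure from depth. The share and its tests were added after the data were seen.

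**Figure D3:**
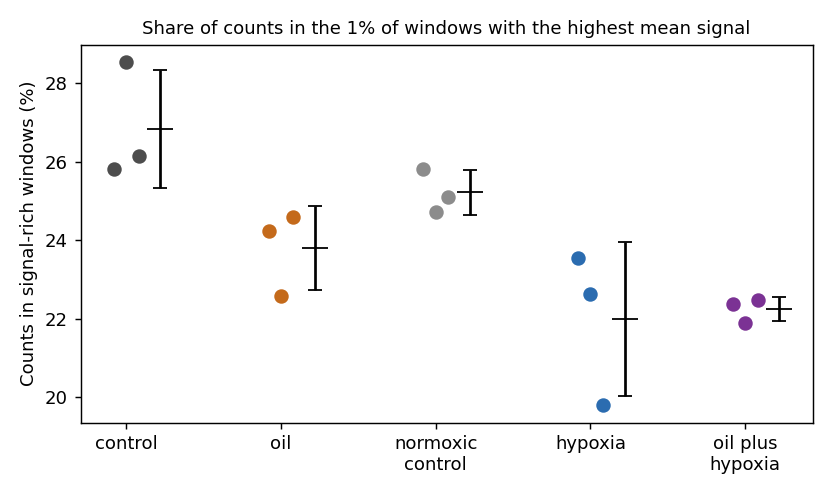
Percentage of each library's counts that lie in the 1% of windows with the highest mean signal (vertical axis, which does not start at 0), by group. Coloured points are the 15 libraries and black marks are group mean and SD. The oil libraries (22.6 to 24.6) lie below the controls (25.8 to 28.5), and the hypoxia (19.8 to 23.6) and oil plus hypoxia libraries (21.9 to 22.5) lie below the normoxic controls (24.7 to 25.8).

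The median log2 difference also changed with the signal level. After oil the median log2 difference went from 0.16 in the decile of lowest signal to -0.15 in the decile of highest signal. It went from 0.19 to -0.06 in hypoxia and from 0.42 to -0.04 in oil plus hypoxia, both against the normoxic control. The trend was not limited to exposed against unexposed libraries: between the 2 untreated groups it went from 0.08 in decile 3 to -0.15 in the highest (-0.04 in the lowest), while between oil plus hypoxia and hypoxia it was 0.26 in the lowest decile and 0.00 to 0.05 in the others. After thinning every library to the smallest one, reads reached 29.7 ± 0.499% of windows in the normoxic control, 33.6 ± 0.856% in hypoxia and 33.8 ± 0.478% in oil plus hypoxia (SD, n = 3, exact permutation p = 0.1 for each). Controls and oil overlapped in this measure, at 29.8 ± 1.20% and 31.4 ± 1.40% (exact permutation p = 0.3).

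**Figure D4:**
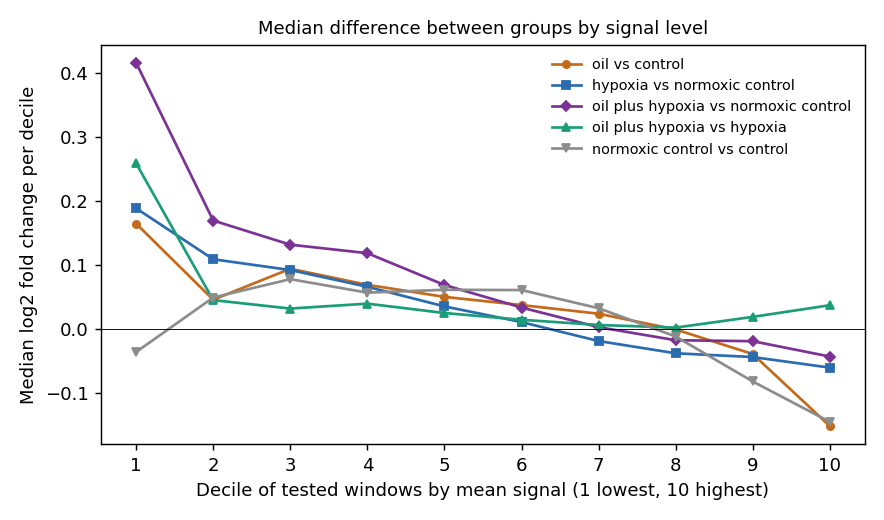
Median log2 fold change of the tested windows (vertical axis) in each decile of mean signal (horizontal axis, 1 lowest to 10 highest), 1 line per comparison. For oil plus hypoxia against the normoxic control the median falls from 0.42 to -0.04, and for oil against control from 0.16 to -0.15.

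Counts were also summed per scaffold. No scaffold passed for oil (0 of 7565, 813 at an unadjusted p under 0.05 by edgeR's quasi-likelihood test) or for hypoxia (0 of 6920, 531 at an unadjusted p under 0.05). Oil plus hypoxia differed from the normoxic control on 84 scaffolds, 12 higher and 72 lower. The scaffold NW_015152275.1 fell from 359 ± 24.9 to 249 ± 2.10 CPM (SD, n = 3, log2 -0.53 ± 0.05 SE, adjusted p 0.00567), and NW_015152745.1 fell from 174 ± 9.81 to 120 ± 2.70 (log2 -0.54 ± 0.05, adjusted p 0.00567). Without oil plus hypoxia replicate 2 or replicate 3, 0 scaffolds were called. Between oil plus hypoxia and hypoxia 3 scaffolds passed, NW_015158671.1 and NW_015151422.1 higher (log2 2.59 ± 0.29 and 0.31 ± 0.04) and NW_015156350.1 lower, and 0 passed without any one oil plus hypoxia library, without hypoxia replicate 2 or with the replicate number as a block.

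Between the untreated groups 605 scaffolds differed, 164 higher and 441 lower in the normoxic control. The mitochondrial genome, NC_028088.1, held 171 ± 9.68 CPM in the normoxic control and 323 ± 44.3 in the control (SD, n = 3, log2 -0.92 ± 0.09 SE, adjusted p 0.00393). After oil it held 241 ± 32.1 CPM against 322 ± 43.1 in controls (log2 -0.42 ± 0.11, adjusted p 0.357). The values were 193 ± 34.5 in hypoxia against 173 ± 9.22 in the normoxic control (adjusted p 0.752) and 150 ± 8.84 in oil plus hypoxia against 173 ± 9.45 (adjusted p 0.144). Without normoxic control replicate 2 the untreated groups differed on 19 scaffolds, and without replicate 3 on 18.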

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

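All tests of explanations in this part were chosen after the results were seen. The effect of oil on methylated DNA signal differed between normal and low oxygen in 6930 of 1757501 windows by a direct test of the difference, which is what drew attention to it. The oil effect was the higher one under hypoxia in 6733 of these windows, with a median log2 of 1.58 under hypoxia and -0.48 in normoxia. Selecting windows by the difference favours such opposite medians. On 200000 of the windows the real grouping called 746, and the highest count among 39 other draws of the 12 libraries into 4 groups was 0, so 1 of 40 splits gave as many. Those draws mix oil plus hypoxia with hypoxia libraries, which differ by themselves (8033 windows), so they do not decide whether chance can be excluded. The call rests on few libraries, since 0 windows passed without oil replicate 2 or control replicate 2. The contrast also carries lane 3, which holds oil plus hypoxia libraries and no others.

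For gains of signal in oil plus hypoxia over the normoxic control (3415 windows), the first pattern weighed, windows were called without 1 normoxic control library, and in them the control libraries of the other set lay above that left-out library by at least 0.937 of the distance at which oil plus hypoxia lay, and by up to 1.06 of it. A candidate explanation is therefore that the normoxic control libraries stand apart from the other untreated libraries in these windows, and hypoxia lay even lower, by log2 values of -0.62, -0.21 and -0.26. Random sampling of unequal numbers of reads alone is argued against, because 471 higher windows were called after every library was thinned to the smallest one, far fewer than before. A bias linked to depth that arose before the counts stays open: in the 9 control, oil and hypoxia libraries these windows had a slope of 1.75 ± 0.30 (SE) on log2 depth within groups, where 1 is proportional, but 0.85 ± 0.28 without hypoxia replicate 3. Lane and pool cannot be told apart from the exposure, since 0 libraries of other groups share lane 3.

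For losses in oil plus hypoxia (5972 windows), the second pattern, the controls of the other set covered 0.447 to 0.576 of the distance from the left-out normoxic control library, and oil without hypoxia lay nearly as low as oil plus hypoxia (log2 -0.63, -0.62 and -0.87 against -0.71, -0.68 and -0.93). Hypoxia lay at -0.27, -0.26 and -0.47, near the controls at -0.32, -0.31 and -0.54. From the normoxic control to oil plus hypoxia, this order of groups is also that of their mean depth. A limit on the number of read positions in deep libraries could also lower the share of strongly covered windows: after a correction with an assumed limit, 2907 of the 5972 windows (48.7%) were still called lower. The median log2 of all 5972 went only from -0.72 (quartiles -0.90 and -0.59) to -0.65 (-0.86 and -0.48), and the 3065 calls that ended went from -0.60 to -0.49 while their median SE rose from 0.11 to 0.12, so they ended by a smaller difference and a larger SE. Both explanations and an effect of the exposure stay open, because the normoxic control also has the lowest mean depth, and the limit is assumed: at NW_015150482.1 the highest count was 504 in controls and 506 in the deeper oil libraries, below the 798 positions assumed, and 969 in oil plus hypoxia, where 1596 were assumed for replicate 1.

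For the lower share of signal-rich windows in exposed libraries, the third pattern, thinning tested a related measure, the windows reached, and not the share itself. After thinning to equal total counts exposed libraries still reached more windows (stratified exact permutation p = 0.00179), although control and oil libraries overlapped and thinning does not undo a limit on counts. This argues against random sampling of unequal numbers of reads alone for the windows reached, and decides nothing about the share. After correction for used positions the summed difference was -5.59 percentage points against -6.13 before (91.2% of it). Without windows holding a count of 200 or more it was -2.63, while the log2 ratios were -0.160, -0.139 and -0.167 against -0.173, -0.197 and -0.180. Since the limit was assumed, a limit on counts stays open as an explanation. Unequal antibody enrichment or library preparation cannot be told apart from an effect of the exposure, since 0 input or spiked-in libraries were analysed here. A bias linked to depth cannot be told apart either, since each exposed group was deeper on average than its unexposed group. That exposure moved methylated reads away from signal-rich windows (stratified exact permutation p = 0.000595) may be kept as a hypothesis only, since the median log2 also fell with signal level between the 2 untreated groups (0.08 in decile 3, -0.15 in decile 10).

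Other groupings of the same libraries were also tested, where 3 against 3 libraries give 10 splits, too few for a share under 0.05. Every other split mixes libraries of the groups compared, so a difference between these groups enters the spread and lowers its calls. Low counts in the other splits are therefore no separate evidence. For windows the real and the highest other counts were 9387 and 101 for oil plus hypoxia against the normoxic control, 8033 and 0 against hypoxia, and 40065 and 0 for the untreated groups, each reached by 1 split. For oil they were 0 and 51 and for hypoxia 0 and 0. A real count of 0 is reached by all 10 splits whatever they give, so these decide nothing. For scaffolds the pairs were 84 and 1, 3 and 0, and 605 and 0, again reached by 1 split each, and 0 and 3 for oil and 0 and 1 for hypoxia, again reached by all 10 of necessity.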

How the results depend on the processing

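Offsets by signal level, thinning, the removal of windows with a count of 200 or more, the edgeR exact test, DESeq2 on 1 kb bins, the correction for used positions, and all alternatives for scaffolds, signal-rich windows, the mitochondrial share and the difference of the oil effects were chosen after the data were seen. Of 106 alternative counts of windows 57 stayed within 1.5-fold, as did 26 of 45 for scaffolds. A count of 0 that stayed 0 was taken as unmoved, and many of the 57 are such counts for oil and hypoxia. All 24 mitochondrial log2 ratios stayed within 1 pooled SD of the main value. For the named regions that passed the threshold, 154 of 160 alternative values kept direction and side of it for oil plus hypoxia against the normoxic control, 108 of 161 against hypoxia and 163 of 164 for the untreated groups, the others no longer passed it, and 0 turned. The regions named for oil and hypoxia had not passed, and 10 of 164 and 6 of 102 values passed newly. Values changed more than these counts show, as from -0.46 to -0.03 with signal-level offsets (NW_015151052.1, oil) or from 6.72 to 0.07 in 1 kb bins (NW_015150567.1, hypoxia). The cause of the changes was not tested, except that fewer libraries or counts leave less power. Promoters, gene bodies, gene lists and CpG offsets were not run.

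For oil, the exact test called 823 windows, DESeq2 1154 bins, and leaving out 1 library gave 0 to 12 (12 without oil replicate 1). For hypoxia these tests called 91 and 31, and leaving out a library gave 0 each time. For oil plus hypoxia against the normoxic control, where 9387 windows were called, a minimum count of 60 gave 15665, 1 kb bins 249, signal-level offsets 5421, thinning 2325, no windows of 200 or more 49, the exact test 27859, DESeq2 23080 and the position correction 5949. Leaving out 1 library gave 2919 (normoxic control replicate 3) to 7530, with over 1.5-fold fewer also without normoxic control replicate 2 or oil plus hypoxia replicate 1, 2 or 3. Against hypoxia (8033), 1 kb bins gave 0, thinning 2028, no windows of 200 or more 5120, the exact test 75379, DESeq2 7634 (5266 higher, 2368 lower), and leaving out 1 library 0 to 10095. For the untreated groups (40065), 1 kb bins gave 2945, thinning 22969, the exact test 82867, DESeq2 8539, and leaving out 1 library 10308 to 35897. For the difference of the oil effects (6930), leaving out 1 library gave 0 to 12519.

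Scaffold calls went from 84 to between 0 and 170 when 1 library was left out for oil plus hypoxia against the normoxic control, from 3 to between 0 and 24 against hypoxia (5 without a minimum count), and from 605 to between 18 and 630 for the untreated groups. The log2 ratio of the signal-rich share was -0.0868 with 5% of windows for oil (-0.173 with 1%). For oil plus hypoxia against the normoxic control it was -0.238 with 0.5%, -0.118 with 5% and -0.121 after the position correction (-0.180 with 1%). Against hypoxia it turned from 0.0170 to -0.0140 with 0.5%, -0.0409 with each library's own 1%, and -0.0281 without windows of 200 or more, and ran from -0.0536 (without hypoxia replicate 3) to 0.0692 with 1 library left out. Summed over both sets, the difference of -6.13 percentage points was -5.06 with 0.5%, -8.19 with 5%, -6.28 with each library's own 1% and -2.63 without windows of 200 or more (stratified exact permutation p = 0.000595 each). In that last setting the removed windows hold many of the counts, and the log2 ratios were -0.160 for oil, -0.139 for hypoxia and -0.167 for oil plus hypoxia against the normoxic control, against -0.173, -0.197 and -0.180.

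With the replicate number as a block, calls fell to 452 windows for oil plus hypoxia against hypoxia, 19858 for the untreated groups and 2211 for the difference of the oil effects, and to 0 and 290 scaffolds in the first and second of these. It moved no other count beyond 1.5-fold. Together with signal-level offsets, the block left 6611 windows for oil plus hypoxia against hypoxia and 27432 for the untreated groups. The numbers do not show pairing: no same-numbered pair correlated above 0.1, and the own number was the best match for 0, 1, 3, 1 and 0 of 3 pairs in the 5 comparisons. Libraries averaged 1.18 to 1.86 counts per window in the normoxic control, 1.62 to 3.10 in hypoxia and 3.16 to 9.67 in the other groups.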

Other observations

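Tests in this part were chosen after the data were seen, and levels are CPM without TMM scaling. Levels at some named regions did not follow the exposures. At NW_015150608.1, 363001 to 363300, signal was 2.13 ± 0.124 CPM per window in the normoxic control and 1.95 ± 0.404 in oil plus hypoxia, but 0.465 ± 0.0469 in hypoxia, 0.659 ± 0.305 in the controls and 1.14 ± 0.406 after oil (SD, n = 3). At NW_015150564.1, 1207801 to 1208200, it was 0.00240 ± 0.00416 in the controls and 0.0192 ± 0.00606 in oil plus hypoxia, against 0.310 ± 0.532 after oil, 0.483 ± 0.197 in the normoxic control and 0.569 ± 0.196 in hypoxia. The oil mean there came with an SD above the mean, from libraries that differed among themselves.

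At NW_015151059.1 both named regions were low in the whole normoxic control set. From 370901 to 373500, signal was 2.72 ± 0.957 in the controls and 1.38 ± 0.199 after oil, and 0.298 ± 0.0763, 0.251 ± 0.0926 and 0.599 ± 0.106 in the normoxic control, hypoxia and oil plus hypoxia. From 161201 to 162300 on NW_015150724.1, the same groups held 6.17 ± 0.956, 5.21 ± 0.728, 2.11 ± 0.291, 2.15 ± 0.745 and 3.19 ± 0.323 CPM. The group means of the mitochondrial share followed that division too, at 320 ± 38.8 and 242 ± 32.5 CPM in control and oil, and 173 ± 8.92, 193 ± 34.5 and 150 ± 8.87 in the other 3 groups, although hypoxia replicate 3 (227) lay above oil replicate 3 (206).

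The highest count of any window lay between 545 and 732 in 14 of the libraries, whose depth ran from 3.07 to 12.2 M reads, and was 1466 in oil plus hypoxia replicate 1. The 92 windows that the authors' deposited table lists as lower after oil reached a median of 49.9% of the 798 assumed read positions, against 4.32% for the 18 listed as higher. Offsets by signal level moved the log2 difference after oil at NW_015151052.1, 407601 to 408000, from -0.46 to -0.03, at NW_015150865.1 from -0.48 to -0.05 and at NW_015150482.1 from -0.48 to -0.07. The correction for used positions left them at -0.44, -0.49 and -0.49.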
